A study of Mus musculus with 20 samples.

How the data were processed

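Bulk RNA sequencing of mouse left ventricle was analysed in 20 libraries, 5 each of Control and dnOGAh-Tg after 2 and after 24 weeks of doxycycline induction. Total RNA had been isolated with a column kit for fibrous tissue. The submitters' processing notes name Trim Galore 0.6.6, cutadapt 2.6, STAR 2.7.3a, R 4.0.3, DESeq2 without a version and the build GRCm39. The read counter, the annotation release and the strand of the libraries are not given in the sources used here, so genes that overlap on opposite strands are not told apart by any statement made. The authors deposited one table per time whose unit is a normalized signal, namely read counts of a gene divided by one size factor per library. Every column was checked for this: 100% of the values above 0 were whole multiples of one step per column within 0.01 of a read, so whole reads were recovered by dividing by that step. The steps of 2 columns lay within 1% of 1, and their values were treated in the same way.

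The tables list 19872 genes at 2 weeks and 19985 at 24 weeks, each with at least 10 reads over the 10 libraries of its time. Recovered reads per library ranged from 22804712 to 50996272. Each time was tested within its own table, since the tables were normalized separately, and levels were not compared across tables. Values were log2 transformed after adding 1, and genes with a value of at least 10 in at least 5 of the 10 libraries were tested, 14584 at 2 weeks and 14676 at 24 weeks. The test was limma-trend (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The difference between times was the contrast of the dnOGAh-Tg minus Control change at 24 weeks with that at 2 weeks, in one fit of the 4 groups over the 14339 genes tested at both times. These tests, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined.

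The 22 gene lists were O-GlcNAc cycling and the hexosamine pathway, fetal and hypertrophy genes, sarcomere, calcium handling and ion channels, oxidative phosphorylation (nuclear and mitochondrial genome), TCA cycle and pyruvate oxidation, fatty acid uptake and oxidation, ketone and branched-chain amino acid catabolism, glycolysis and glucose uptake, regulators of mitochondrial biogenesis, mitochondrial dynamics and mitophagy, mitochondrial ribosome, cytosolic ribosome, extracellular matrix, integrated stress response and serine synthesis, unfolded protein response of the endoplasmic reticulum, heat shock proteins, antioxidant genes, circadian clock, immediate early genes and interferon response. The 11 cell marker lists were fibroblast, endothelial, mural, macrophage, lymphocyte, neutrophil, erythroid, adipocyte, atrial, epicardial and Schwann cell. Lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over the 57 list tests of both times, and for each list the called members were counted over all genes and adjusted over the list alone.

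The genes named in the text were chosen by a rule. It takes, per time, the 8 largest rises and the 8 largest falls among called genes with a group mean of at least 50 in 1 group and groups that do not overlap, leaving out predicted gene models. It adds 22 fixed genes whatever their values, and up to 4 members per list with the smallest p-values, of which the text gives the more telling ones. For the difference between times it takes the 6 most positive and the 6 most negative called genes. Of the genes the rule takes at 24 weeks, 1 is not reported here. Genes named outside the rule are marked as chosen after their values were seen.

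The alternatives fixed in advance were pseudocounts of 0.5 and 5, no filter and a stricter filter of 50, quantile normalization, rescaling with TMM factors, robust variance moderation, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, blocks for the replicate number and for the title code, all 20 libraries in one fit, a limit of 1.5-fold, an adjusted p under 0.01, leaving out each library, an estimated correlation in camera, and fry. Alternatives added after seeing the data left out the F11 dnOGAh-Tg libraries, all F11 libraries or the F19 libraries, took a split of the libraries on Gm37194 (at most 5 counts or more) as a covariate, combined that with leaving out the F11 dnOGAh-Tg libraries, or removed a loess trend (span 0.5) over transcript length and GC content. Length and GC came from an annotation of the older build GRCm38, joined by gene identifier alone. Adjusted p-values of the authors were not used here, and sex was not a covariate, since all libraries had the same pattern of Xist and Ddx3y.

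The procedure was tested on simulated data at the same sizes and depth. At 2 weeks it recovered 79% of genes simulated at a log2 change of 1 and 100% at 2, with 8% false calls, and at 24 weeks 86% and 100%, with 3.81% false. For the difference between times it recovered 64.8% and 99.5%, with 4.55% false. In the simulation all dnOGAh-Tg libraries of a time had the same change, and each gene was drawn independently. Neither a weaker response in the F11 libraries nor the library split was imitated. The recovered shares therefore do not say what could be found in the real libraries of 2 weeks. Libraries of the same group were compared for duplicates, and the smallest chi-square per degree of freedom between 2 of them was 12.1, far from that of repeated sequencing of one library. Whole-group splits of the same libraries were counted for each comparison, 100 drawn of the 126 possible at each time.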

Results

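RNA was sequenced from the left ventricle of mice carrying a dominant-negative form of O-GlcNAcase made in the heart under doxycycline (dnOGAh-Tg) and of Control mice, after 2 or 24 weeks of induction. O-GlcNAcase, encoded by Oga, removes O-GlcNAc, a single sugar that Ogt attaches to serine and threonine of nuclear, cytoplasmic and mitochondrial proteins. The series title places the comparison in the study of lasting O-GlcNAc elevation, growth of the heart and mitochondrial function. Each of the 4 groups held 5 libraries, 20 in all. Reads assigned to the listed genes ranged from 22804712 to 31906006 per library in Control and from 24641225 to 50996272 in dnOGAh-Tg at 2 weeks. At 24 weeks they ranged from 24240718 to 30610824 in Control and from 23953851 to 37844796 in dnOGAh-Tg. Xist lay between 0 and 17.7 normalized counts and Ddx3y between 2116 and 3848 over the 20 libraries. Values below are normalized read counts, given as mean ± SD with n = 5 libraries per group, and changes are log2 differences of dnOGAh-Tg minus Control with their standard error (SE) from limma. The labels do not say outright that each library comes from a separate animal, so the p-values measure the spread between these libraries.

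Oga (ENSMUSG00000025220, chromosome 19, 45738698 to 45772276 on GRCm39) was higher in every dnOGAh-Tg library than in any Control library of its time. At 24 weeks it rose from 3139 ± 466 to 38287 ± 15191, a log2 change of 3.53 (SE 0.23, limma adjusted p = 1.26e-06), and the 5 dnOGAh-Tg libraries lay at 6.90 to 17.9 times the Control mean. At 2 weeks the means were 3549 ± 706 and 35067 ± 26149 (log2 change 2.79, SE 0.57, adjusted p = 0.118), and the libraries were far apart. Those whose titles carry the code F11 had 8608 and 6406 counts, 2.43 and 1.81 times the Control mean. The F13 library had 56985, 16.1 times the Control mean, and the F14 libraries had 61206 and 42127, 17.2 and 11.9 times that mean. Leaving out the F11 dnOGAh-Tg libraries, an alternative added after Oga had been seen, selects on Oga itself. Its change of 3.92 (adjusted p = 1.14e-06, within 1.14e-06 to 0.503 over its alternatives) is therefore no evidence on this gene. Whether reads of the transgene align to Oga is not given in the sources used here, so the level stands for the endogenous gene and the transgene together.

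**Figure D1:**
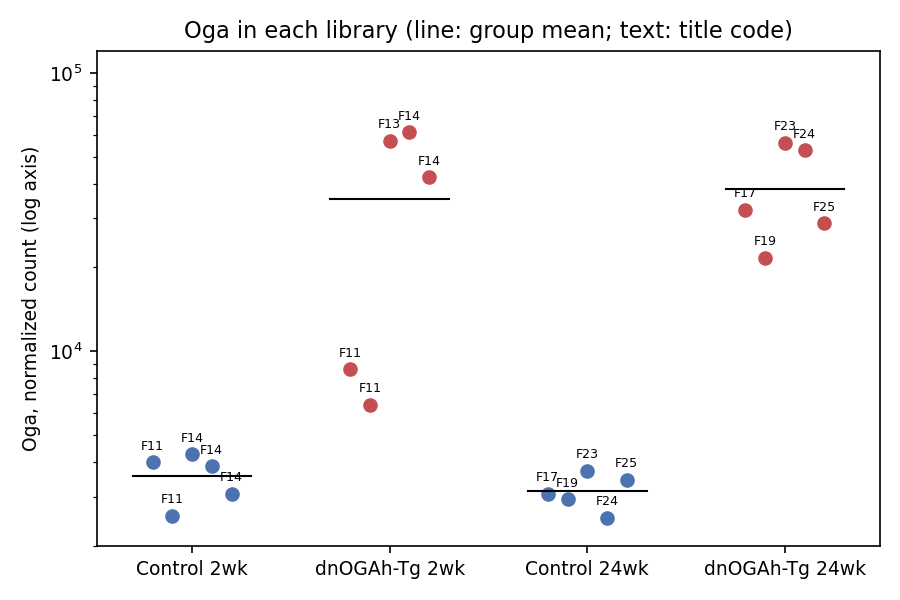
Normalized read count of Oga on a log axis in each of the 20 libraries, by group and time, with the title code beside each point and a line at each group mean. At 2 weeks the F11 dnOGAh-Tg libraries lie at 8608 and 6406 and the other 3 between 42127 and 61206, while the Control libraries lie between 2565 and 4269.

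The rest of the list for O-GlcNAc cycling and the hexosamine pathway, which makes the sugar donor, held few calls at 24 weeks. Besides Oga, Uap1l1, related to the enzyme that makes the donor, rose by 0.60 (SE 0.14). Gnpda2, a glucosamine-phosphate deaminase, fell (log2 change -0.54, SE 0.10). Of 14 tested members 2 rose and 1 fell, the same counts when adjusted over the list alone. Ogt was at -0.01 (SE 0.18, limma adjusted p = 0.984). Gfpt1 and Gfpt2, which catalyse the entry step of the pathway, were at 0.10 (SE 0.16, adjusted p = 0.700) and -0.02 (SE 0.21, adjusted p = 0.957). The list as a whole was not called at 24 weeks (camera adjusted p = 0.320) or at 2 weeks (0.432), where 1 member passed when adjusted over the list alone. Fry, which tests members against no change and not against other genes, gave 0.00468 at 24 weeks with Oga itself among the members (within 0.00468 to 0.568 over the alternatives).

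The 24-week comparison asks how the ventricle differed after long induction. Sln, a small inhibitor of the calcium pump of the sarcoplasmic reticulum that is abundant in the atria, rose from 6.83 ± 4.92 to 619 ± 425 (log2 change 6.33, SE 0.46, limma adjusted p = 2.15e-06). Adamts8, a secreted metalloprotease (ENSMUSG00000031994, chromosome 9, 30853858 to 30875134), rose from 22.9 ± 3.84 to 918 ± 148 (5.26, SE 0.16, adjusted p = 1.06e-09), the smallest adjusted p of this time. Star, which carries cholesterol to the inner mitochondrial membrane, rose from 24.3 ± 12.3 to 837 ± 249.9 (5.14, SE 0.31). Ankrd2, an ankyrin-repeat protein of stretched muscle, rose from 14.4 ± 4.24 to 399 ± 170.2 (4.64, SE 0.29). The remaining genes among the 8 largest rises by the naming rule were Atp1b4 (log2 change 5.77, SE 0.45), Chodl (5.35, SE 0.75), the carboxylesterase Ces5a (4.75, SE 0.48) and the glutamate receptor subunit Grin2a (4.50, SE 0.48).

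By the same rule the largest falls at 24 weeks were smaller in log2 change than the largest rises. Several of those rises started near the floor, where the added count of 1 weighs on the change. In Control, Chodl was at 0 except in Control 3 (12.5), Grin2a was at most 12.8 and Ces5a at most 26.0. The sizes of rises and falls are therefore not strictly comparable. Mylk4, a myosin light chain kinase of striated muscle (ENSMUSG00000044951, chromosome 13, 32884810 to 32967937), went from 6038 ± 1696 to 297 ± 71.3 (-4.33, SE 0.20, limma adjusted p = 6.90e-08). The cytochrome P450 gene Cyp2b10 went from 869 ± 428 to 35.2 ± 20.3 (-4.58, SE 0.45). Others were the serine protease gene Tmprss13 (-4.37, SE 0.54), Eprn (-3.96, SE 0.35), the fatty acid desaturase gene Scd4 (-3.88, SE 0.43), Tnip3 (-2.71, SE 0.30) and the lipid transporter gene Abca12 (-2.63, SE 0.30). In all, limma called 3296 of 14676 genes at 24 weeks, 1662 higher and 1634 lower in dnOGAh-Tg. Of these, 561 rose and 321 fell by at least 2-fold. In 2448 genes (16.7%) the groups did not overlap, where chance gives 0.794%. Cyp2b10, Ces5a and Scd4 have close relatives in their families, and how reads matching several copies were counted is not given in the sources used here, so these 3 values are less certain.

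Most genes of the fetal and hypertrophy list rose at 24 weeks. Nppa, which encodes atrial natriuretic peptide, rose from 14300.1 ± 6458 to 208402 ± 76406 (3.97, SE 0.38, limma adjusted p = 1.81e-05). Nppb rose from 15927 ± 8476 to 37273 ± 11405 (1.37, SE 0.36, adjusted p = 0.0156) with groups that overlapped. Skeletal actin Acta1 rose from 27301 ± 14580.5 to 176619 ± 37603 (2.84, SE 0.31). The growth factor gene Tgfb2 rose from 581 ± 92.0 to 1541 ± 164 (1.41, SE 0.12) and Ccn2, a secreted matrix-cell protein, from 6009 ± 1453 to 18522 ± 3925 (1.63, SE 0.18). The slow myosin gene Myh7b fell from 2211 ± 332 to 571 ± 202 (-2.01, SE 0.20). Myh7, also in this list, was lower but not called, and its values stand with the sarcomere genes below. Of 23 tested members 15 rose and 2 fell, or 16 and 2 adjusted over the list alone, with a median log2 change of 0.92. The list was called by camera (adjusted p = 2.25e-05), with adjusted p = 0.483 with an estimated correlation.

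The sarcomere list went both ways at 24 weeks. Myh6, the main adult ventricular myosin of the mouse, fell from 656284 ± 13331 to 362647 ± 76193 (-0.88, SE 0.17, limma adjusted p = 0.00246), a call that ended with quantile normalization (-0.39, adjusted p = 0.133, the highest over its alternatives, the lowest being 4.52e-09). Myh7, the slow and fetal ventricular myosin, belongs to the fetal and hypertrophy list and is not counted here. It went from 78488 ± 30439.8 to 51166 ± 26649.7 (-0.67, SE 0.33, limma adjusted p = 0.165) and was not called. It passed without dnOGAh-Tg 2 (-0.92, adjusted p = 0.0338, within 0.0338 to 0.326 over its alternatives). Tcap, a cap protein of titin, rose from 27460.0 ± 6679 to 54243 ± 13005 (0.98, SE 0.19). Of 22 tested members 4 rose and 4 fell, or 4 and 5 adjusted over the list alone, and the list was not called (camera adjusted p = 0.231).

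Genes of calcium handling and of ion channels fell at 24 weeks. Atp2a2, the calcium pump of the sarcoplasmic reticulum, fell from 409032 ± 26281 to 215364 ± 31497 (-0.94, SE 0.14, limma adjusted p = 0.000516). Its inhibitor Pln fell from 211393 ± 17874 to 105137 ± 12805 (-1.01, SE 0.13, adjusted p = 0.000125). The potassium channel subunit gene Kcnv2 went from 621 ± 32.9 to 142 ± 27.3 (-2.14, SE 0.12). The gap junction gene Gja1 went from 16113 ± 1599 to 6306 ± 1457 (-1.38, SE 0.16) and the calcium channel subunit gene Cacnb2 from 1959.7 ± 184 to 967 ± 139 (-1.03, SE 0.11). Of 30 tested members 19 fell and 1 rose, or 21 and 1 adjusted over the list alone, with a median of -0.55. The list was called lower by camera (adjusted p = 1.16e-08), with adjusted p = 0.152 with an estimated correlation.

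Fuel oxidation fell broadly at 24 weeks. In fatty acid uptake and oxidation, Etfa, which passes electrons from acyl-CoA dehydrogenases, fell from 28810.1 ± 2815 to 15223 ± 577 (-0.92, SE 0.09, limma adjusted p = 1.93e-05). The carnitine palmitoyltransferase gene Cpt2 fell from 7717 ± 724 to 4195 ± 433 (-0.88, SE 0.10) and Decr1 from 12254 ± 1392 to 5925 ± 798 (-1.05, SE 0.11). The mitochondrial carrier gene Ucp3 fell from 1333 ± 584 to 297 ± 67.8 (-2.09, SE 0.24). Cpt1b, the muscle carnitine palmitoyltransferase of the outer membrane, fell from 243 ± 26.1 to 171 ± 20.3 (-0.51, SE 0.12, adjusted p = 0.00932). This call ended with all 20 libraries in one fit (adjusted p = 0.115, within 7.86e-04 to 0.115 over its alternatives). Of 34 tested members 28 fell and 0 rose by limma, 29 fell adjusted over the list alone, and the median was -0.76. In the TCA cycle and pyruvate oxidation, citrate synthase Cs went from 43788 ± 2667 to 26057 ± 2040.4 (-0.75, SE 0.09). Suclg2, a subunit of succinyl-CoA ligase, went from 5074 ± 442 to 2887 ± 269.6 (-0.81, SE 0.09). Of 26 members 20 fell, 25 adjusted over the list alone, with a median of -0.53. Pdk4, which inhibits pyruvate dehydrogenase, was at -0.87 (SE 0.30, adjusted p = 0.0559) and not called. It passed without Control 4 (adjusted p = 0.0434), without dnOGAh-Tg 4 (0.00614) and with the length and GC trend removed (0.0416), within 0.00614 to 0.140 over its alternatives. In the catabolism of ketones and branched-chain amino acids, Mccc2 (-0.92, SE 0.10) and Bckdhb (-0.65, SE 0.09) fell. Of 22 members 17 fell, 18 adjusted over the list alone, with a median of -0.56. The camera adjusted p of these 3 lists were 8.33e-17, 9.81e-13 and 5.38e-10, with adjusted p = 0.265, 0.152 and 0.152 with an estimated correlation.

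**Figure D2:**
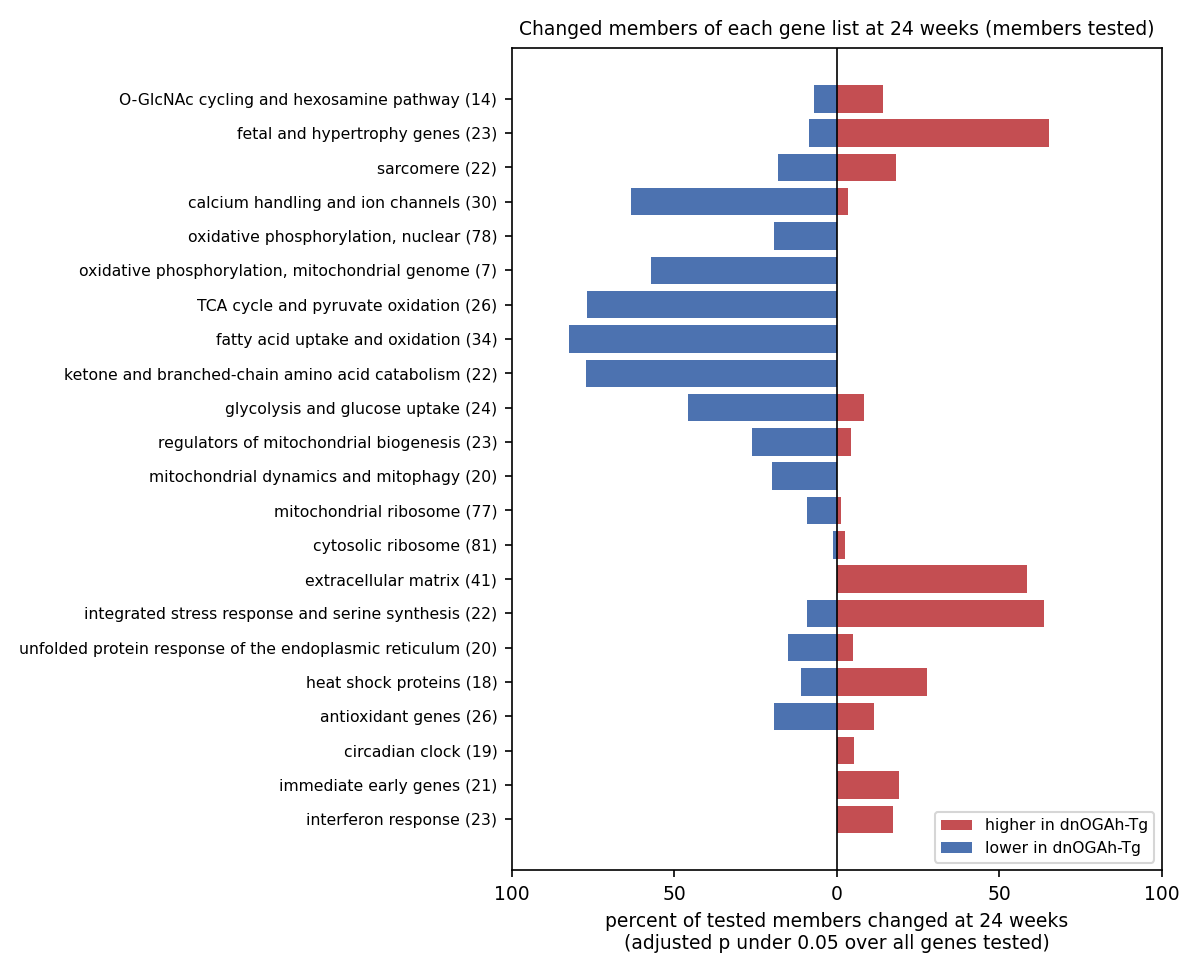
Percent of the tested members of each of the 22 gene lists that limma called higher (red) or lower (blue) in dnOGAh-Tg at 24 weeks. The highest shares of lower members are in fatty acid oxidation (28 of 34), ketone and branched-chain amino acid catabolism (17 of 22) and the TCA cycle (20 of 26). The highest shares of higher members are in the fetal and hypertrophy list (15 of 23), the integrated stress response (14 of 22) and the extracellular matrix (24 of 41).

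Respiratory chain genes had smaller medians than fuel oxidation at 24 weeks. Among nuclear genes of oxidative phosphorylation, Sdha, the flavoprotein of complex II, fell from 44222 ± 1712 to 25766 ± 2288 (-0.78, SE 0.09, limma adjusted p = 6.95e-05). The ATP synthase gene Atp5a1 fell from 157762 ± 10673 to 107107 ± 6811 (-0.56, SE 0.11). Of 78 tested members 15 fell and 0 rose, the same counts when adjusted over the list alone, with a median of -0.34 (camera adjusted p = 9.00e-09, and adjusted p = 0.155 with fry and 0.592 with an estimated correlation). Of 7 protein-coding genes of the mitochondrial genome 4 fell, 7 adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.00291, and adjusted p = 0.551 with an estimated correlation). Reads on mitochondrial genes made up 14.9 to 17.1% of the Control libraries and 11.9 to 13.5% of the dnOGAh-Tg libraries. Quantile normalization ended this list's call (adjusted p = 0.750, within 2.90e-04 to 0.750 over its alternatives) and turned mt-Nd2 at 24 weeks, a complex I subunit, from -0.50 (SE 0.14, adjusted p = 0.0236) to 0.02 (adjusted p = 0.921). The mt-Nd2 call also ended without Control 2 (adjusted p = 0.0531), Control 5 (0.0642), dnOGAh-Tg 1 (0.0519) or dnOGAh-Tg 4 (0.0511), and with no filter (0.0703), a replicate block (0.0690) or the F19 libraries left out (0.0656), within 1.495e-07 to 0.921 over its alternatives.

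Ppargc1a, a coactivator of mitochondrial biogenesis, fell at 24 weeks from 2486 ± 197 to 1384 ± 296 (-0.87, SE 0.13, limma adjusted p = 0.000516). The nuclear receptor gene Rxrg fell from 2310.2 ± 209 to 1396 ± 211 (-0.73, SE 0.11). The nuclear receptor genes Ppara (-0.64, SE 0.32, adjusted p = 0.172) and Esrra (-0.20, SE 0.12, adjusted p = 0.258) were not called. The list of regulators of mitochondrial biogenesis had 6 of 23 members lower and 1 higher, 10 and 1 adjusted over the list alone (median -0.26, camera adjusted p = 0.00237, and adjusted p = 0.265 with an estimated correlation). Mfn1, which fuses mitochondria, fell from 11817 ± 536 to 8164 ± 743 (-0.54, SE 0.08). It was 1 of 4 members of 20 to fall in the list of mitochondrial dynamics and mitophagy, also 4 adjusted over the list alone. That list was not called (adjusted p = 0.0712), but passed without Control 1 (0.0457), dnOGAh-Tg 1 (0.0300) or dnOGAh-Tg 2 (0.0439). It also passed with no filter (0.0364), with fry (0.0246) and with the length and GC trend removed (0.0424), within 0.0246 to 0.568 over its alternatives. The mitochondrial ribosome list, with Mrpl39 at -0.80 (SE 0.13), had 7 of 77 members lower and 1 higher, 5 and 1 adjusted over the list alone (median -0.09, adjusted p = 0.0362, and adjusted p = 0.775 with an estimated correlation). Its call ended without Control 2, 4 or 5 or dnOGAh-Tg 3, 4 or 5 (adjusted p 0.0707 to 0.338), with the stricter filter (0.0570), with quantile normalization (0.146) and with fry (0.497, within 6.20e-05 to 0.775 over its alternatives).

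Glycolysis and glucose uptake moved in both directions at 24 weeks. The glycolytic regulator Pfkfb1 fell from 384 ± 117 to 88.0 ± 21.6 (-2.08, SE 0.25, limma adjusted p = 0.000108). Hexokinase Hk2 fell from 9974 ± 637 to 7014 ± 675 (-0.51, SE 0.09), and the lactate transporter gene Slc16a3 rose from 70.0 ± 20.7 to 198 ± 51.2 (1.497, SE 0.24). The glucose transporter genes Slc2a1 (0.05, SE 0.13, adjusted p = 0.820) and Slc2a4 (-0.21, SE 0.09, adjusted p = 0.105) were not called. Slc2a4 passed with the length and GC trend removed (-0.29, adjusted p = 0.00979, within 0.00979 to 0.668 over its alternatives). Of 24 members 11 fell and 2 rose, 14 and 3 adjusted over the list alone (median -0.28, camera adjusted p = 0.00168, and adjusted p = 0.483 with an estimated correlation). Quantile normalization ended the list's call (adjusted p = 0.120, within 1.54e-04 to 0.483 over its alternatives).

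Matrix genes rose at 24 weeks. The collagen-binding proteoglycan genes Fmod and Bgn rose from 26.3 ± 11.7 to 330.1 ± 140.4 (3.61, SE 0.36, limma adjusted p = 2.26e-05) and from 7625 ± 1629 to 16163 ± 2608 (1.09, SE 0.15). Postn, a matrix protein of activated fibroblasts, rose from 1596 ± 1144 to 4602 ± 1868 (1.66, SE 0.34, adjusted p = 0.00386). The collagen gene Col1a1 rose from 4123 ± 1272 to 7317 ± 1764 (0.85, SE 0.20, adjusted p = 0.00872). The groups overlapped in both. Of 41 tested members 24 rose and 0 fell, and 27 rose adjusted over the list alone, with a median of 0.64 (camera adjusted p = 3.80e-09, and adjusted p = 0.551 with an estimated correlation).

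Genes of the integrated stress response and serine synthesis rose at 24 weeks as well. Mthfd2, a mitochondrial folate enzyme, went from 129 ± 79.9 to 1072 ± 271 (3.21, SE 0.33, limma adjusted p = 2.96e-05). The amino acid transporter gene Slc7a5 went from 241 ± 20.7 to 756 ± 115 (1.64, SE 0.11) and asparagine synthetase Asns from 86.6 ± 23.4 to 356 ± 114 (2.01, SE 0.23). Of 22 members 14 rose and 2 fell, the same counts adjusted over the list alone (median 0.66, camera adjusted p = 1.83e-05, and adjusted p = 0.483 with an estimated correlation). The list of the unfolded protein response of the endoplasmic reticulum was not called (median -0.05, adjusted p = 0.210). In it Hspa5, the main chaperone of that compartment, fell from 18273 ± 1806 to 11720.5 ± 761 (-0.64, SE 0.09), with 3 of 20 members lower and 1 higher, also adjusted over the list alone. Among heat shock proteins Hsp90aa1 rose from 3294 ± 479 to 5173 ± 555 (0.66, SE 0.11), and 5 of 18 members rose and 2 fell, also adjusted over the list alone. The list was not called (adjusted p = 0.0712). It passed without Control 2 (0.0159), dnOGAh-Tg 3 (0.0443) or dnOGAh-Tg 4 (0.0395) and with the F19 libraries left out (0.0323). It also passed with quantile normalization (0.00232), with the library split as a term (0.0470) and with the length and GC trend removed (0.0482), within 0.00232 to 0.592 over its alternatives. Antioxidant genes were not called as a list (median -0.17, adjusted p = 0.211). Secreted glutathione peroxidase Gpx3 rose (1.12, SE 0.16) and mitochondrial superoxide dismutase Sod2 fell (-0.64, SE 0.08). Of 26 members 3 rose and 5 fell, or 4 and 6 adjusted over the list alone.

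Markers of other cell types moved apart at 24 weeks. Endothelial markers fell, among them the VEGF receptor genes Kdr, from 8165 ± 756 to 5377 ± 1032 (-0.62, SE 0.13, limma adjusted p = 0.00445), and Flt1 (-0.45, SE 0.09). Of 14 members 7 fell, 10 adjusted over the list alone (median -0.36, camera adjusted p = 2.19e-04, and adjusted p = 0.483 with an estimated correlation). Fibroblast markers had 4 of 14 higher and 1 lower, 5 and 1 adjusted over the list alone, with Lum at 0.77 (SE 0.14). Their median was 0.18 (adjusted p = 0.0448, and adjusted p = 0.592 with an estimated correlation), and the call ended without Control 2, 3 or 5 or dnOGAh-Tg 1, 2 or 5 (adjusted p 0.0563 to 0.120), with the F19 libraries left out (0.211) and with fry (0.138, within 0.0146 to 0.592 over its alternatives). Of 15 macrophage markers 1 rose, Fcgr1 (0.92, SE 0.26, adjusted p = 0.0246, 0.0612 without dnOGAh-Tg 5, 0.0536 with the F19 libraries left out, 0.0708 with all 20 libraries in one fit and 0.00578 to 0.0708 over its alternatives), and 0 adjusted over the list alone. The macrophage median was 0.40 (adjusted p = 0.0398, and adjusted p = 0.592 with an estimated correlation), and the call ended without Control 2, 3 or 5 or dnOGAh-Tg 1 or 5 (adjusted p 0.0517 to 0.134), with the F19 libraries left out (0.0857) and with fry (0.215, within 0.00397 to 0.592 over its alternatives). All 4 tested erythroid markers fell, also adjusted over the list alone. Alas2, the heme synthesis enzyme of red cells, went from 935 ± 262 to 431 ± 47.2 (-1.08, SE 0.17) and the globin gene Hba-a1 was at -0.79 (SE 0.15). Hba-a1 has a near-identical neighbour, so its value is less certain.

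The 2-week comparison asks what differed early, and the dnOGAh-Tg libraries differed widely among themselves. Nppa stood at 9000.0 and 15734 counts in the F11 dnOGAh-Tg libraries, 99561 in the F13 library and 116150.0 and 84967 in the F14 libraries, against 2081 to 11414 in Control (log2 change 3.57, SE 0.70, limma adjusted p = 0.118). The 11414 was in Control 2, a library that also carried atrial genes, as given at the end. The other Controls lay at 2081 to 3243, below both F11 dnOGAh-Tg libraries. Nppb stood at 8123 and 15570.3 in the F11 libraries and at 47512, 26013 and 28823 in the others, all above the 4024 to 6711 of Control (1.94, SE 0.37, adjusted p = 0.118). Ucp3 stood at 1388 and 980.4 in the F11 libraries and at 398, 270.4 and 272 in the others, against 797 to 1869.7 in Control (-1.24, SE 0.43, adjusted p = 0.137). Nmrk2, a nicotinamide riboside kinase of muscle, averaged 83.8 ± 53.7 in Control and 764 ± 643 in dnOGAh-Tg (2.87, SE 0.64). Timp1, an inhibitor of matrix proteases, averaged 31.9 ± 31.0 and 329 ± 268 (2.86, SE 0.83). Mthfd2 averaged 99.2 ± 32.2 and 238 ± 56.5 with groups apart (1.27, SE 0.23, adjusted p = 0.118).

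At 2 weeks with all 10 libraries the count depended on the tool. Limma called 0 of 14584 genes (smallest adjusted p = 0.118), with 3551 genes at an unadjusted p under 0.05, where chance gives 729.2. EdgeR called 0 genes and DESeq2 called 850, 607 higher and 243 lower. Limma called 241 with a block for the replicate number. With all 20 libraries of both times in a single fit over 14339 genes it called 1157. That fit takes a variance per gene shared by the 4 groups, so the wide spread of the 2-week dnOGAh-Tg group makes up only a part of it. In 460 genes (3.15%) the groups did not overlap, where chance gives 0.794%. Once the F11 dnOGAh-Tg libraries were left out, limma called 4929 genes, 2351 higher and 2578 lower. Among them were Nppa (4.79, adjusted p = 6.97e-05), Timp1 (4.35, adjusted p = 1.98e-04) and Nmrk2 (3.91, adjusted p = 3.24e-04). Others were Atp2a2 (-0.97, adjusted p = 0.00798), Pln (-0.77, adjusted p = 0.00213), Ucp3 (-2.003, adjusted p = 3.32e-04) and Ppargc1a (-0.73, adjusted p = 0.00619). The libraries left out were chosen after Oga had been seen and also lay lowest of the dnOGAh-Tg libraries in Nppa. These calls and their adjusted p are therefore not free of that choice. Over all alternatives the adjusted p ranged from 3.05e-06 to 0.483 for Nppa and from 0.00798 to 0.905 for Atp2a2. With all F11 libraries left out limma called 3241, without dnOGAh-Tg 1 alone 3366, without dnOGAh-Tg 2 alone 0 and without Control 5 alone 447. With the F11 dnOGAh-Tg libraries left out and the split described below as a term it called 912, against Control 5 alone. Over the alternatives the smallest and the highest count at 2 weeks were 0 and 4929.

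The fixed genes gave these values at 2 weeks with all libraries, none of them called by limma. DESeq2 called Acta1 (adjusted p = 0.0165, within 0.00481 to 0.299 over its alternatives) and Pln (0.0434, within 0.00213 to 0.749). Over all 43 genes named for this time DESeq2 called 26, and limma with all 20 libraries in one fit called 23. Acta1 was at 0.99 (SE 0.26), Postn at 1.13 (SE 0.45), Ccn2 at 0.55 (SE 0.28) and Col1a1 at 0.43 (SE 0.30). Atp2a2 was at -0.55 (SE 0.28), Pln at -0.52 (SE 0.17), Myh6 at -0.47 (SE 0.21) and Myh7 at -0.24 (SE 0.12). Ppargc1a was at -0.48 (SE 0.19), Ppara at -1.23 (SE 0.59), Esrra at 0.11 (SE 0.12), Pdk4 at -0.42 (SE 0.38) and Cpt1b at -0.42 (SE 0.27). Slc2a1 was at -0.13 (SE 0.16), Slc2a4 at 0.01 (SE 0.09), Ogt at -0.16 (SE 0.16), Gfpt1 at -0.23 (SE 0.19) and Gfpt2 at 0.04 (SE 0.16).

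By gene lists, ribosomal protein genes and nuclear genes of the respiratory chain were higher at 2 weeks and fuel oxidation lower, each by camera with its preset correlation and with 0 members called by limma over all genes. None of these calls held with an estimated correlation. On the cytosolic ribosome and nuclear oxidative phosphorylation lists Control 5 lay 0.59 and 0.78 above the mean of Controls 1 to 4. The dnOGAh-Tg mean lay 0.61 and 0.56 above it (0.08 to 0.96 and 0.25 to 0.79 over the libraries), and a library split that may bear on this is described below. The cytosolic ribosome list had a median of 0.43 (adjusted p = 1.07e-16, and 0.568 with an estimated correlation, 36 of 81 members higher adjusted over the list alone), with Rpl29 at 1.60 (SE 0.36) and Rpl41 at 1.501 (SE 0.34). Nuclear oxidative phosphorylation had a median of 0.41 (adjusted p = 8.24e-11, and 0.568 with an estimated correlation, 29 of 78 higher adjusted over the list alone), with the complex I gene Ndufb3 at 1.15 (SE 0.27) and the complex IV gene Cox5b at 1.03 (SE 0.26). The mitochondrial ribosome list, with Mrpl23 at 1.57 (SE 0.39), had a median of 0.21 (adjusted p = 1.53e-07, and 0.592 with an estimated correlation). With the length and GC trend removed the medians of these 3 lists were 0.24, 0.14 and 0.06 (adjusted p = 1.93e-07, 0.00283 and 0.0213). Interferon response (median 0.63, adjusted p = 2.23e-06), macrophage markers (0.80, adjusted p = 1.41e-05, 8 of 15 higher adjusted over the list alone) and matrix genes (0.34, adjusted p = 2.91e-04) were also higher. So were immediate early genes (0.38, adjusted p = 0.00141), the integrated stress response (0.31, adjusted p = 0.00181, 8 higher and 1 lower of 22 adjusted over the list alone) and the fetal and hypertrophy list (0.17, adjusted p = 0.0274, 8 of 23 higher adjusted over the list alone). Within the stress response Slc7a5 was at 0.70 (SE 0.15), Atf4 at 0.53 (SE 0.14) and Phgdh at 0.83 (SE 0.22). Where no such count is given it was 0. For these lists adjusted p = 0.551 to 0.592 with an estimated correlation.

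The lower lists at 2 weeks were led by calcium handling and ion channels (median -0.40, camera adjusted p = 2.17e-05, 3 of 30 lower adjusted over the list alone), with the potassium channel genes Kcnq1 at -0.56 (SE 0.15) and Kcnh2 at -0.48 (SE 0.13). Fatty acid uptake and oxidation was lower too (median -0.28, adjusted p = 1.44e-04), with Cpt2 at -0.62 (SE 0.16). The TCA cycle followed (-0.29, adjusted p = 4.50e-04, 3 of 26 lower adjusted over the list alone), with Suclg2 at -0.50 (SE 0.14) and Pdk2 at -0.42 (SE 0.10). Ketone and branched-chain amino acid catabolism (-0.28, adjusted p = 5.48e-04) and regulators of mitochondrial biogenesis (-0.20, adjusted p = 7.56e-04) were lower as well. The circadian clock list, with Per3 at -0.66 (SE 0.15) and Cry2 at -0.48 (SE 0.12), had a median of -0.16 (adjusted p = 0.0408, 4 of 19 lower adjusted over the list alone). For these lists adjusted p = 0.483 to 0.568 with an estimated correlation. In all, 0 of the 57 list tests of both times passed that way, against 30 with the preset one. Without Control 5 the fetal (adjusted p = 0.129) and matrix (0.0764) calls ended. The circadian call ended without Control 4 (0.0610), Control 5 (0.0919), dnOGAh-Tg 2 (0.0788) or dnOGAh-Tg 3 (0.0523). It also ended with the F11 dnOGAh-Tg libraries left out (0.0864), with all F11 libraries left out (0.0640), with the former and the split as a term (0.0661), with quantile normalization (0.0730), with the stricter filter (0.0570) and with the length and GC trend removed (0.132). With fry the other 14 calls of 2 weeks ended (adjusted p 0.0789 to 0.298). Over all alternatives the adjusted p ranged from 1.21e-04 to 0.568 for the fetal, 2.31e-18 to 0.592 for the matrix and 0.0168 to 0.483 for the circadian list.

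**Figure D3:**
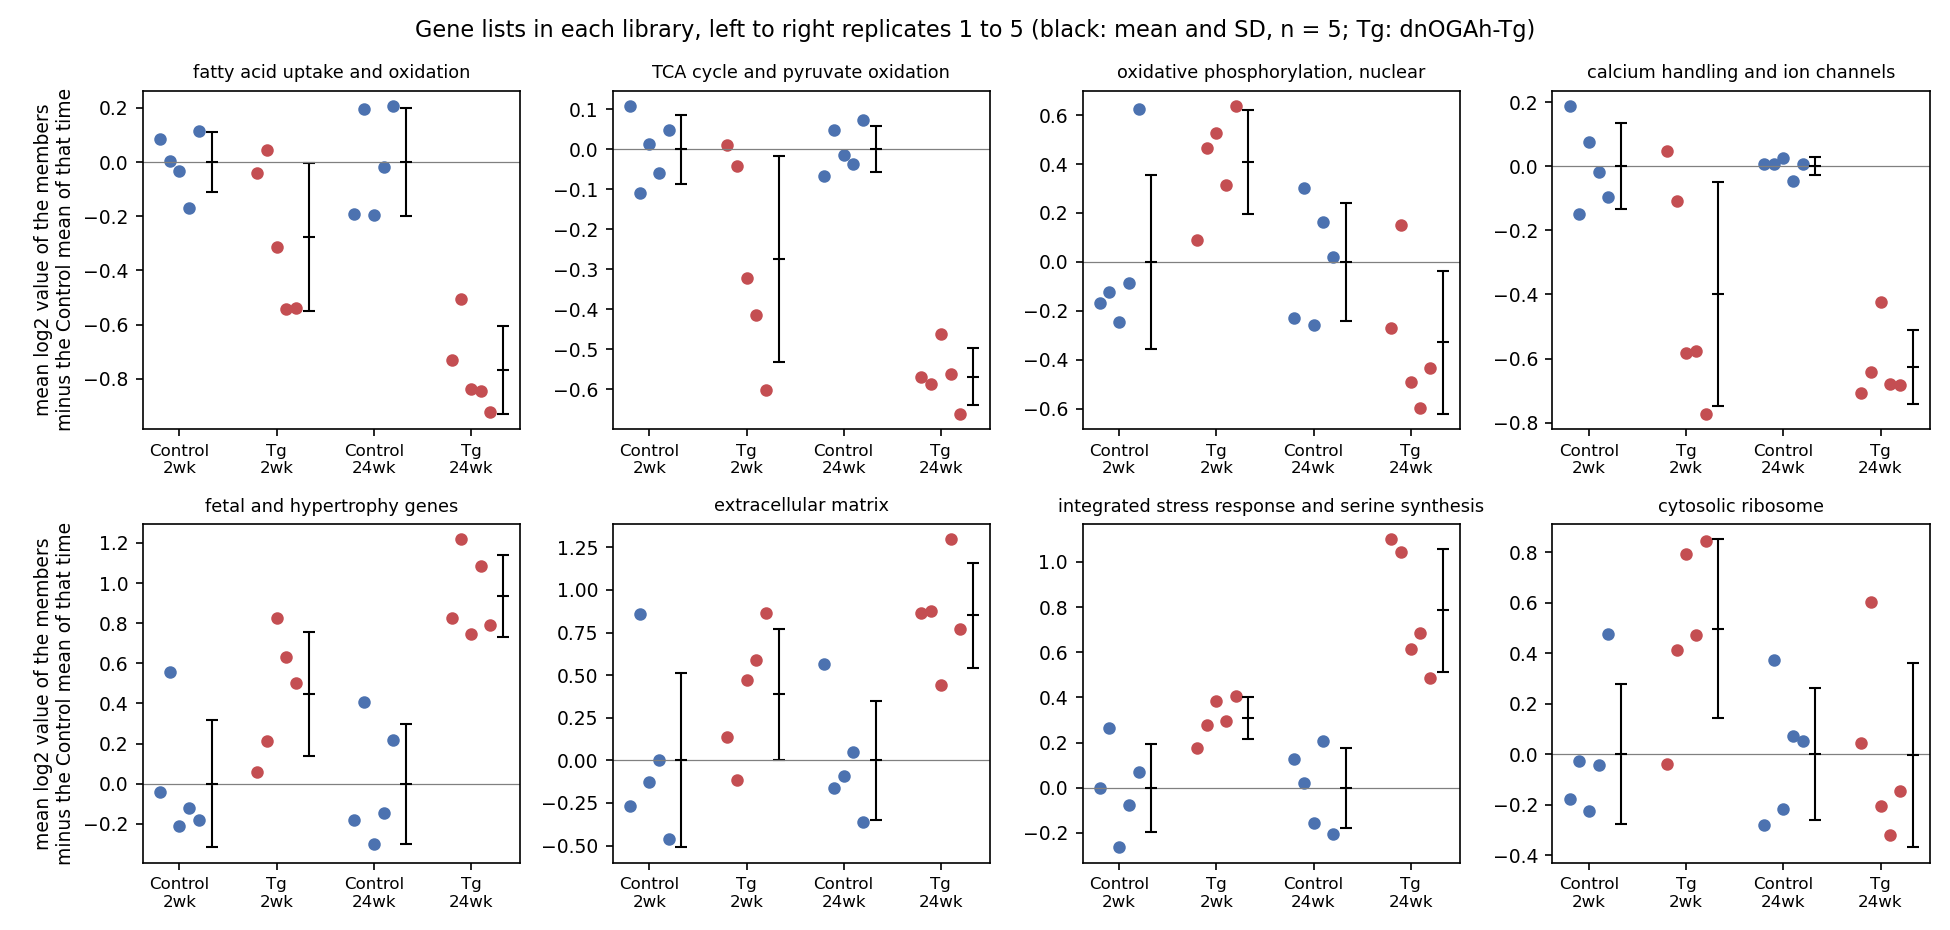
Mean log2 normalized count of the members of 8 gene lists in each library, minus the Control mean of that time, with the group mean and SD in black (n = 5). At 24 weeks the dnOGAh-Tg mean lies at -0.77 in fatty acid oxidation and at 0.93 in the fetal and hypertrophy list, while at 2 weeks Control 5 lies among the dnOGAh-Tg libraries in nuclear oxidative phosphorylation and the cytosolic ribosome.

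A split of the libraries that the labels do not give runs along the groups at 2 weeks. The predicted gene Gm37194, chosen after its values were seen, was at 0 to 1.26 counts in Controls 1 to 4 of 2 weeks and at 3.05 and 3.56 in the F19 libraries of 24 weeks (Control 2 and dnOGAh-Tg 2). It was at 48.3 to 218 in all others. Cebpb, a transcription factor also chosen after its values were seen, was at 124 to 164 in Controls 1 to 4 of 2 weeks and at 1866 in Control 5. On the nuclear oxidative phosphorylation and cytosolic ribosome lists Control 5 lay 0.78 and 0.59 above the mean of Controls 1 to 4, where the dnOGAh-Tg mean lay 0.56 and 0.61 above it. The low side held Controls only and the high side held 1 Control. A fit with the split as a term, an alternative chosen after seeing the data, therefore compares the dnOGAh-Tg libraries of 2 weeks with Control 5 alone, and its values rest on that library. Limma called 10 genes at 2 weeks in it, all higher. Nuclear oxidative phosphorylation turned lower there (camera adjusted p = 1.80e-07), as did the mitochondrial ribosome (0.00128), and the cytosolic ribosome (0.833) and the integrated stress response (0.0723, and 0.118 with the F11 dnOGAh-Tg libraries also left out) were not called. Over all alternatives the adjusted p of these 4 lists reached 0.568, 0.592, 0.833 and 0.551, from 1.11e-22, 1.45e-12, 7.97e-22 and 2.38e-04.

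The difference between the times asks whether the effect of the transgene changed with the length of induction. Ryr3, a calcium release channel, went from -0.81 (SE 0.44) at 2 weeks to 3.22 (SE 0.24) at 24 weeks (difference 4.02, SE 0.54, limma adjusted p = 5.34e-04). Adamts8 went from 1.57 to 5.26 (difference 3.69, SE 0.51, adjusted p = 5.58e-04). Other genes more positive at 24 weeks were Lrrn1 (4.02, SE 0.81, adjusted p = 0.0152), Fam180a (3.98, SE 0.84, adjusted p = 0.0190), the G protein subunit gene Gnal (3.87, SE 0.63, adjusted p = 0.00350) and Mlph (3.54, SE 0.61, adjusted p = 0.00453). Strit1, which encodes a small peptide that raises activity of the calcium pump, went from 1.45 to -1.40 (difference -2.85, SE 0.57, adjusted p = 0.0152), and Mrpl23 from 1.57 to -0.80 (-2.37, SE 0.49, adjusted p = 0.0177). Tnip3 (-2.50, SE 0.40, adjusted p = 0.00280), Eprn (-2.43, SE 0.49, adjusted p = 0.0152), Tmprss13 (-3.16, SE 0.80, adjusted p = 0.0458) and Cyp2b10 (-3.10, SE 0.75, adjusted p = 0.0365) were also more negative at 24 weeks.

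In all, the change differed between the times in 252 of 14339 genes by limma, 154 more positive and 98 more negative at 24 weeks. With the library split as a term, which leaves Control 5 as the only Control to compare with at 2 weeks, 2 genes passed. The 12 genes named for the difference all missed the threshold in that fit, with adjusted p 0.110 to 0.759. With all F11 libraries left out 34 genes passed, 31 of them among the 252. Of the 12 named genes Tmprss13, Cyp2b10, Strit1, Tnip3, Eprn, Mrpl23 and Lrrn1 then missed the threshold (adjusted p 0.0574 to 0.185). Leaving out only the F11 dnOGAh-Tg libraries gave 313, 168 of them among the 252, without Tmprss13 (0.0869) and Cyp2b10 (0.0747). These 2 also missed it with the F19 libraries left out (0.108 and 0.0912), and Tmprss13 with a pseudocount of 0.5 (0.0552). Over all alternatives the highest adjusted p of the 12 genes lay between 0.110 and 0.759. Leaving out 1 library gave 100 to 683 genes. The count was lower by over 1.5 times without Control 1, 2, 3 or 4 of 2 weeks (125, 137, 138 and 112) or dnOGAh-Tg 2 of 2 weeks (128). It was lower as well without Control 1, 2, 4 or 5 of 24 weeks (163, 132, 104 and 114) or dnOGAh-Tg 1 or 4 of 24 weeks (100 and 138). It was 683 without Control 5 of 2 weeks and 406 without Control 3 of 24 weeks. The Tmprss13 call ended (adjusted p 0.0555 to 0.101, within 0.00491 to 0.390 over all its alternatives) on leaving out any library except Control 5 and dnOGAh-Tg 3 and 4 of 2 weeks and Control 3 of 24 weeks. The Cyp2b10 call ended (adjusted p 0.0501 to 0.0840, within 0.00705 to 0.580 over all its alternatives) on leaving out any library except Control 5 and dnOGAh-Tg 3 and 5 of 2 weeks and Control 3 and dnOGAh-Tg 5 of 24 weeks.

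Of 28 lists tested for the difference, 18 were called by camera and 0 with an estimated correlation. Nuclear oxidative phosphorylation was the clearest, at a median of 0.41 at 2 weeks and -0.34 at 24 weeks (median difference -0.67, adjusted p = 2.31e-31, and adjusted p = 0.419 with an estimated correlation). The cytosolic ribosome (-0.41, adjusted p = 8.68e-13, and 0.470 with an estimated correlation), the mitochondrial ribosome (-0.33, adjusted p = 1.80e-12, and 0.468) and fatty acid oxidation (-0.48, adjusted p = 6.25e-11, and 0.419) were more negative at 24 weeks. The fetal and hypertrophy list (0.41, adjusted p = 0.00209, and 0.419), the integrated stress response (0.36, adjusted p = 2.13e-04, and 0.419) and matrix genes (0.28, adjusted p = 0.00343, and 0.615) were more positive. With the F11 dnOGAh-Tg libraries left out the fetal (adjusted p = 0.0992) and matrix (0.281) differences were not called. With the split as a term, so against Control 5 alone at 2 weeks, the mitochondrial ribosome (0.769) and matrix (0.0549) differences changed sign, and the cytosolic ribosome (0.641) and fetal (0.139) differences were not called. Nuclear oxidative phosphorylation was then at a median of -0.22 at 2 weeks and -0.34 at 24 weeks, lower at both times, with adjusted p = 0.0211 for the difference. Over all alternatives the adjusted p ranged from 0.001505 to 0.746 for the fetal, 4.02e-04 to 0.858 for the matrix and 1.60e-14 to 0.769 for the mitochondrial ribosome difference. It ranged from 1.41e-20 to 0.641 for the cytosolic ribosome and from 5.99e-37 to 0.419 for nuclear oxidative phosphorylation.

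Across the 14339 genes tested at both times, the log2 changes of 2 and 24 weeks had a Pearson r of 0.532 and a Spearman rho of 0.549, over genes, which are not independent replicates. Of the genes called at 24 weeks, 87.0% had the same sign at 2 weeks. With all libraries 0 genes passed at both times, since limma called 0 at 2 weeks. With the F11 dnOGAh-Tg libraries left out, 707 genes were higher at both times, where independent sets would share 255, and 967 were lower at both, where they would share 289, while 7 and 21 went opposite ways. Those libraries were left out after Oga had been seen, so these counts are not free of that choice.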

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

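Among the tests below, those on the Oga ratio, on carried-over reads in each F11 library, on Control 5 against the other Controls, on Myl7 against Sln and on the 5 atrial genes were chosen only after the result was seen, as were the alternatives that leave out F11 libraries, take the library split as a term or remove the length and GC trend. A library far from the others of its group was sought in 260 groups of 5, and 24 of them (9.23%) had one, where chance gives about 1 in 20, or 13.

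The first pattern is the unequal response at 2 weeks. On a score of 774 genes called at 24 weeks, the F11 dnOGAh-Tg libraries stood at 0.05 and 0.09, the F13 library at 0.92 and the F14 libraries at 0.89 and 0.95, against 0.32 in Control 2 and -0.14 to -0.06 in the other Controls. Control 5 and the F11 libraries, on the same side of the library split as the others, reached at most 0.0987 of the lowest of the other 3 scores, where the split as a cause would need 0.5. The low F11 scores are part of the pattern, so of these only Control 5, at -0.14, bears on that. All dnOGAh-Tg libraries of 2 weeks lie on one side of the split, so it cannot set them apart from each other. A Control library with a wrong label and carried-over reads is argued against for dnOGAh-Tg 1, where Oga would need 10.1% of reads from the others and 27 further genes showed a median share of 0.558% (quartiles -0.804% and 4.10%), 0.0551 of it. For dnOGAh-Tg 2 it stays open, since the 5.73% that Oga needs lies within the quartiles of these genes (-1.78% and 8.93%, median 1.17%, 0.204 of it). A candidate explanation that stays open is a lower transgene level in the F11 animals, whose Oga was at most 0.204 of the lowest of the others, and other differences between litters or dates that the F codes may stand for were not tested.

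The second pattern is the higher nuclear oxidative phosphorylation and cytosolic ribosome lists at 2 weeks. Control 5 departed from Controls 1 to 4 by at least 0.966 of what the dnOGAh-Tg mean did in both lists (0.78 and 0.59 against 0.56 and 0.61), so the library split may account for both rises. The single dnOGAh-Tg libraries, all on the high side, lay at 0.25 to 0.79 and at 0.08 to 0.96. Controls 1 to 4 had an SD of 0.07 and 0.10. The split cannot set the dnOGAh-Tg libraries apart from each other, so it leaves their spread unexplained. Transcript length and GC stay undecided, because removing their trend left both called at the preset correlation (adjusted p = 0.00283 and 1.93e-07, where an estimated correlation without that step gave 0.568 for each) but brought the medians from 0.41 to 0.14 and from 0.43 to 0.24, the smaller keeping 0.343 of its size. An early effect of the transgene on these genes stays open, as at 2 weeks Control 5 alone of the Controls lies on the dnOGAh-Tg side of the split.

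The third pattern is Sln at 24 weeks, at 1358 in dnOGAh-Tg 4 and 322 to 540.0 in the other dnOGAh-Tg libraries, against 2.53 to 12.5 in Control. Atrial tissue in the sample is argued against for dnOGAh-Tg 1, 2, 3 and 5, where Myl7, abundant in atrial muscle, was at most 0.0214 of Sln. In dnOGAh-Tg 4 it remains a candidate source, since Myl7 (912), Myl4 (4528), Bmp10 (105), Dkk3 (1031) and Sln (1358) were all 5 highest in that library among those of 24 weeks. A rise of Sln in the ventricle of the other 4 libraries, a biological explanation that the groups offer, stays open as a hypothesis.

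Chance was weighed by regrouping the libraries. At 24 weeks the real split was 1 of 100 with as many genes (3296, highest other 270). That is the lowest rank 100 drawn splits allow, so it makes chance unlikely but cannot exclude it. At 2 weeks the real count was 0, which all 100 splits must reach, so that rank says nothing on chance. The highest other split gave 4950. The 3 splits with most genes (4950, 3752 and 3283) all put dnOGAh-Tg 1 with Controls 1, 3 and 4 and apart from dnOGAh-Tg 3, 4 and 5, which points to a structure of the samples. At an unadjusted p under 0.05 the real split was among 4 of 100 (3551 genes, highest other 6573 for Controls 1 to 4 with dnOGAh-Tg 1 against the rest). That highest regrouping differs from the library split only in dnOGAh-Tg 1, so the rank of the real split does not exclude chance. With the F11 dnOGAh-Tg libraries left out the real split was 1 of 56 (4929 genes, highest other 3925 for Controls 1, 3 and 4 against the rest). Those libraries were left out for their Oga level, so the rank is not free of that choice. For the difference between times the real split was among 3 of 100 (252 genes, highest other 4550). The far larger count of another regrouping points to a structure of the samples too, so this rank does not exclude chance either.

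The change differed between 2 and 24 weeks, by a test of the difference, in 252 genes (2 with the split as a term, against Control 5 alone at 2 weeks) and in 18 lists (0 with an estimated correlation). The log2 differences were -3.16 for Tmprss13, -3.10 for Cyp2b10, -2.85 for Strit1, -2.50 for Tnip3, -2.43 for Eprn, -2.37 for Mrpl23, 4.02 for Ryr3, 4.02 for Lrrn1, 3.98 for Fam180a, 3.87 for Gnal, 3.69 for Adamts8 and 3.54 for Mlph.

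The gap of the farthest library to the nearest, over the range of its group, passed 0.71 in these groups of 5. Control 5 of 2 weeks was highest in Cox5b (0.932), Strit1 (0.891), Ndufb3 (0.884), Mrpl23 (0.841), Rpl41 (0.837), Rpl29 (0.797) and Slc2a4 (0.750). Control 2 of 2 weeks was highest in Nppa (0.875, at 11414), Timp1 (0.867) and Slc7a5 (0.768), and dnOGAh-Tg 1 of 2 weeks in Ppara (0.746, at 919). Among 24-week Controls, Control 3 was highest in Chodl (1, at 12.5 with the others at 0) and Ces5a (0.771), Control 1 in Postn (0.919, at 3636) and Grin2a (0.737), and Control 5 in mt-Co1 (0.789). In the 24-week dnOGAh-Tg group, dnOGAh-Tg 4 was highest in Myl4 (0.990, at 4528), Sln (0.789) and Dkk3 (0.739) and lowest in Bckdhb (0.858) and Slc2a4 (0.730). Fcgr1 was highest in dnOGAh-Tg 5 (0.909, at 116), Bhlhe41 in dnOGAh-Tg 3 (0.720), and Gnpda2 was lowest in dnOGAh-Tg 1 (0.7999).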

How the results depend on the processing

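The alternatives that leave out F11 or F19 libraries, take the library split as a term or remove the length and GC trend were chosen only after the result was seen. With the split as a term Control 5 is the only Control compared at 2 weeks. The 24-week count of 3296 stayed within 1.5 times under every alternative except a limit of 1.5-fold (1842) and an adjusted p under 0.01 (1814), where the stricter threshold is the cause, and ranged from 2524 to 3183 on leaving out 1 library. Pseudocounts, filters, TMM rescaling and robust moderation left the 2-week count at 0 by limma. DESeq2 gave 850, all 20 libraries in one fit 1157, the F11 dnOGAh-Tg libraries left out 4929, all F11 libraries left out 3241, the split as a term 10, both together 912, and leaving out 1 library 0 to 3366. The cause was not tested. Genes changed at both times numbered 0, and 444 with all 20 libraries in one fit, 1674 with the F11 dnOGAh-Tg libraries left out, 1424 with all F11 libraries left out, 1 with the split as a term, 568 with both together and 0 to 1124 without 1 library. The difference between times (252) went to 34 with all F11 libraries left out, 131 with the F19 libraries left out, 2 with the split as a term, 3 with the F11 dnOGAh-Tg libraries also left out, 456 with the length and GC trend removed and 100 to 683 without 1 library. The cause was not tested for either.

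Same-numbered libraries were not alike enough to count as pairs (r from -0.21 to 0.38 at 2 weeks and from -0.15 to 0.52 at 24 weeks, 2 of 5 pairs over 0.1 each time). At 24 weeks each title code holds 1 Control and 1 dnOGAh-Tg library of the same number, so a replicate block is a title code block too, and it gave 3921 genes. At 2 weeks a title code block gave 0 genes. A replicate block gave 241 genes at 2 weeks, 422 for the difference and 81 at both times, and the cause was not tested. The replicate number at 2 weeks joins Control 3 of code F14 with dnOGAh-Tg 3 of code F13, so this block does not follow the title codes.

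Of 57 list tests 30 passed with the preset correlation, 0 with an estimated one and 14 with fry. These reversed, and the cause was not tested. At 24 weeks mt-Nd2 went to 0.019 with quantile normalization. At 2 weeks with the split as a term these lists reversed (adjusted p): nuclear oxidative phosphorylation (1.80e-07), mitochondrial ribosome (0.00128), antioxidant genes (0.00614) and adipocyte (0.0444). With the F11 dnOGAh-Tg libraries also left out nuclear oxidative phosphorylation (0.0208) and the mitochondrial ribosome (0.574) did. For the difference the mitochondrial ribosome (0.769), extracellular matrix (0.0549) and antioxidant (0.728) lists reversed with the split as a term, and ketone and branched-chain amino acid catabolism (0.548) and extracellular matrix (4.02e-04) with the F11 dnOGAh-Tg libraries also left out. Of 43 named genes at 2 weeks, 34 became called with the F11 dnOGAh-Tg libraries left out and 0 with the split as a term. Quantile and TMM scaling shifted the median of all genes by little (medians -0.02 and -0.00495 at 2 weeks). That median does not speak for single genes or lists. At 24 weeks quantile normalization ended the calls of Myh6, mt-Nd2 and the mitochondrial genome, glycolysis and mitochondrial ribosome lists, while the heat shock list passed with it. The authors' adjusted p-values and a sex covariate were planned and not run. Genes below 10 counts in over 5 libraries were not tested, which bounds what this depth can show.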

Other observations

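The fits with F19 or F11 libraries left out, those with the split as a term and those with the length and GC trend removed were chosen only after the result was seen. Lists not described above held few calls at 24 weeks. In the cytosolic ribosome list the muscle form Rpl3l fell from 7052 ± 788 to 4250.5 ± 932 (log2 change -0.75, SE 0.14, limma adjusted p = 0.00200). The general form Rpl3 rose from 2979 ± 564 to 4611 ± 858 (0.63, SE 0.15), and 2 of 81 members rose and 1 fell, also adjusted over the list alone. That list was not called (median -0.01, camera adjusted p = 0.976) but was lower without dnOGAh-Tg 2 (adjusted p = 0.00246, within 0.00246 to 0.996 over its alternatives). Of 21 immediate early genes 4 rose, also adjusted over the list alone, among them the transcription factor gene Egr2 from 37.7 ± 23.0 to 133 ± 56.0 (1.85, SE 0.37). The list was not called (median 0.15, adjusted p = 0.124) but passed without Control 2 (0.0427) or Control 3 (0.0475), within 0.0427 to 0.662 over its alternatives. Of 23 interferon response genes 4 rose, 2 adjusted over the list alone, with Ifit3 at 0.89 (SE 0.25, adjusted p = 0.0198). That call ended without Control 4 (0.0516) or dnOGAh-Tg 5 (0.0537) and with all 20 libraries in one fit (0.161), within 0.00453 to 0.161 over its alternatives. The list was not called (median 0.16, adjusted p = 0.0864) but passed without Control 5 (0.0119), dnOGAh-Tg 1 (0.0233) or dnOGAh-Tg 2 (0.0287), with a replicate block (0.0496) and with the F19 libraries left out (0.0403), within 0.0119 to 0.702 over its alternatives. In the circadian clock list the repressor gene Bhlhe41 rose (0.63, SE 0.14), the only call of 19, also adjusted over the list alone (median 0.04, adjusted p = 0.649).

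Among markers of other cells, 3 of 12 mural markers fell and 1 rose at 24 weeks, also adjusted over the list alone. Abcc9, a channel subunit that heart muscle also makes, went from 13184 ± 1457 to 3323 ± 892 (-2.02, SE 0.16, limma adjusted p = 5.19e-06). The mural list was not called (median -0.28, camera adjusted p = 0.0712) but passed without Control 3 (0.0277), dnOGAh-Tg 4 (0.0441) or dnOGAh-Tg 5 (0.0232), with no filter (0.0334) and with a replicate block (0.0496), within 0.0232 to 0.592 over its alternatives. Of 5 epicardial markers 1 rose, the keratin gene Krt18 from 40.5 ± 15.2 to 332 ± 90.1 (3.05, SE 0.28), also adjusted over the list alone (median 0.78, list adjusted p = 0.463). Schwann cell markers had 1 of 6 higher, also adjusted over the list alone (median 0.08, adjusted p = 0.604), and adipocyte markers 0 of 7 either way (median -0.27, adjusted p = 0.852). Too few lymphocyte, neutrophil, erythroid and atrial markers were measured for a set test. By limma 0 of 4 lymphocyte (median 0.38) and 0 of 4 neutrophil markers (median -0.39) were called at 24 weeks, and 2 of 4 atrial markers rose, Sln and Dkk3, or 4 adjusted over the list alone. Dkk3 went from 126 ± 52.2 to 499 ± 306 (1.91, SE 0.36), and its call ended with all 20 libraries in one fit (adjusted p = 0.0730, within 5.73e-07 to 0.0730 over its alternatives). The atrial light chain gene Myl4 was at 1.91 (SE 0.86, adjusted p = 0.131), and passed without dnOGAh-Tg 4 (0.85, adjusted p = 0.00510) and in edgeR (0.0249), within 0.00510 to 0.211 over its alternatives.

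At 2 weeks the lists not called were sarcomere (camera adjusted p = 0.649), the mitochondrial genome (median -0.19, 0.163), glycolysis (0.115, 3 lower adjusted over the list alone, with Pfkfb1 at -0.71, SE 0.16, and Eno1 at -0.48, SE 0.13) and mitochondrial dynamics (0.527). Nor were the unfolded protein response (0.112, 6 higher adjusted over the list alone), heat shock proteins (0.119, 1 higher) and antioxidant genes (0.210, 2 higher and 2 lower) called. The marker lists of fibroblasts (0.847, 1 lower adjusted over the list alone), endothelium (0.157), mural cells (0.282), adipocytes (0.717, with a median of -0.02 and a mean of 0.04) and Schwann cells (0.164) were not called either. Without Control 3 glycolysis passed (0.0434), without Control 5 antioxidant genes (0.0312), without Control 1 mural markers (0.0403), and without dnOGAh-Tg 5 heat shock proteins (0.00982), the unfolded protein response (0.0262), the mitochondrial genome (0.0370) and endothelium (0.0374). Heat shock proteins passed with quantile normalization (0.0426), and glycolysis (0.00656) and the mitochondrial genome (0.0212) with the length and GC trend removed. With the split as a term, so against Control 5 alone, glycolysis (0.00133), the mitochondrial genome (0.00893), mitochondrial dynamics (0.00342), the unfolded protein response (0.00887), antioxidant genes (0.00614) and adipocyte markers (0.0444) passed. With the F11 dnOGAh-Tg libraries left out as well, glycolysis (0.00885), mitochondrial dynamics (0.00744) and the unfolded protein response (0.0319) did. Over all alternatives the adjusted p reached 0.568, 0.802, 0.959, 0.592, 0.922 and 0.917 for these 6 lists and 0.858 for heat shock proteins. By limma 0 of 3 lymphocyte, 2 neutrophil, 4 erythroid, 3 atrial and 3 epicardial markers were called, and adjusted over the list alone 2 lymphocyte, 1 neutrophil and 1 epicardial marker were higher. The counts at an unadjusted p under 0.05 and by the other tools stand with the 2-week gene count of 0.

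Single Control libraries carried genes of other tissue. Control 2 of 2 weeks had the atrial genes Myl7 at 2652, Myl4 at 5052, Sln at 1112 and Dkk3 at 1823 counts. The next highest Control was Control 5, with 7.25, 258, 60.1 and 165. The atrial gene Bmp10 was at 62.2 in Control 5, at 1.26 in Control 2 and at 0 in the other libraries of 2 weeks. Control 5 of 24 weeks had the liver genes Alb at 4295 and Apoa1 at 551, and the other libraries of that time had at most 234 and 31.0. These genes, except those of the atrial list, were chosen after their values were seen.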
